A study of Mus musculus with 5 samples.

How the data were processed

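RNA sequencing was done on white adipose tissue (WAT) of mice. The labels give 2 libraries from wild-type (WT) mice and 3 from mice with a knockout (KO) of Otud3, 1 library per mouse. They also give the cell type as adipocyte, but name no step that would part fat cells from the other cells of the tissue, and no fat depot, sex or age. RNA was isolated with a Qiagen column kit, messenger RNA was captured on poly-T beads, and libraries were read on an Illumina HiSeq X-ten. The submitters' notes list HISAT2 2.0.4, StringTie and edgeR with the mouse build mm10, without saying which tool gave the counts.

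The authors deposited a single table of 23452 Ensembl genes. Per the file headers it holds counts for each library, which are whole numbers and carry no normalization. The deposited FPKM values divide each count by a gene length and by the total of the library. The length implied by count and FPKM was checked for 9579 genes with at least 200 counts and was equal between libraries within a relative difference of 1.3e-05. The authors' group values are the mean FPKM of the KO and of the WT libraries, and the deposited log2 fold changes are the log2 ratio of these means with no pseudocount. The authors' p-values carry a Benjamini-Hochberg adjustment, here called the authors' q. Of the gene symbols, 27 had been turned into dates and were restored from the gene IDs, and the 50 entries that share a symbol were kept apart by ID. Of the 23300 IDs found in the mouse GENCODE annotation of release 21, 23282 overlapped the annotated position and 18530 had the same start and end.

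All tests of the text start from the counts. The 5 libraries held 19396261 to 21294308 counts. Genes were filtered with filterByExpr of edgeR 4.0.16 by genotype (minimum count 10, minimum total 15), which left 17301 genes. Libraries were scaled by TMM, with factors of 0.965 to 1.029, and a quasi-likelihood model with genotype as its only term was fitted with robust empirical Bayes (glmQLFit and glmQLFTest, R 4.3.3). Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 0.295. Normalised read counts are given as CPM, the edgeR unit of counts scaled to the TMM-scaled library total, and fold changes are KO over WT. No block was used, since nothing in the labels ties a WT mouse to a KO mouse.

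Gene lists were tested as sets with camera of limma 3.58.1, with a preset correlation of 0.01 between genes, on the 32 lists with at least 5 tested members. Adjusted p-values of lists are over these 32. Each list was tested again with the correlation estimated from the data. In that form camera also uses the few residual degrees of freedom of the libraries, so that a lost call cannot be laid to correlation alone. For the clock list the estimate was 0.0191, near the preset, yet the unadjusted camera p went from 0.000791 to 0.0504. Each list was also tested with fry, which asks whether its genes move on balance one way (direction) or in either direction (mixed). For members of a list the p-value was also adjusted over the list alone. The test of each gene and list, the 32 lists, the rule for naming genes and most of the alternatives were set before the data were examined. The lists came from general knowledge of white fat, of the tissues that lie beside it and of the topic of the series.

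Genes were named by this rule. Otud3 came first. For each direction, genes past the threshold with at least 1 CPM on average and no overlap between groups were to be named up to 12. Where fewer than 6 passed, the genes of smallest p were named up to 6, as values that did not pass. Each list gave up to 4 members past the threshold or else its 2 members of smallest p. All tested sex-linked genes and Ppard, Crebbp and Sirt1 were always given. Not every gene that the rule picks is described in the text. Predicted genes, pseudogenes and segments of antigen receptors were not named by the rule. Any other gene in the text was chosen after its values were seen. A fold against a group with a count of 0 in every library is given as a lower bound against 3 counts over the group. Such a bound covers counting error only.

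DESeq2 came with its own size factors and its own gene filter (19339 genes tested), and camera with an estimated correlation came with fewer degrees of freedom. Each other alternative changed one choice. The alternatives were the median-of-ratios size factors of DESeq2, upper-quartile scaling, DESeq2 1.42.0 with its Wald test, limma-voom and the edgeR exact test with tagwise dispersion. Others were no low-count filter, a filter at 1 CPM in 2 libraries, robust empirical Bayes off and a replicate block. An added threshold of an absolute log2 fold change of 1 was used too, and each library was left out in turn. A fit with 1 WT library left assumes that it varies like the KO libraries. For the lists, genes of cell type lists were also removed from the other lists. Further alternatives were chosen after seeing the data: the mean log2 CPM of the epididymis and testis list as a covariate beside genotype, and the tests without genes that differ at least 1.5-fold between WT 1 and WT 2. The covariate was lower in each KO library than in both WT libraries, so that it overlaps with genotype. Leaving out genes by their WT spread favours genes whose WT values lie close by chance, so that their p-values can be too small. Alternatives meant for a table of transcripts or of normalized values alone did not apply. 

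The fit was tested on simulated counts with the same group sizes. At an adjusted p under 0.05 it recovered 26% of 50 genes changed 2-fold, 76% of those changed 4-fold and 90% each of those changed 8-fold and 16-fold. It also called 21 unchanged genes in that simulation, and 1 gene in a simulation without any change. In the data, 182 genes were at least 8-fold lower and 5 at least 8-fold higher at an unadjusted p under 0.05 in this fit. None of them passed after adjustment, so that the simulated shares do not describe such genes. In simulated data camera called a list raised 1.5-fold and called 0 unchanged lists. Genes were drawn independently there, so that this says nothing about lists whose members vary together. The correlation estimated in the data was 0.333 for the epididymis and testis list, 0.746 for the erythrocyte list and 0.0191 for the clock list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.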

Results

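White fat of 2 wild-type (WT) and 3 Otud3 knockout (KO) mice was sequenced, 1 library per mouse. Library totals were 21294308 counts for WT 1, 20170732 for WT 2, 19396261 for KO 1, 20173377 for KO 2 and 20694573 for KO 3. Between 20399 and 21941 genes had a count in a library. WT 2 stood apart from the others on the first principal component of log2 normalised read counts, which took 51.5% of the variance: its score was 99.1, while the other 4 libraries lay between -42.4 and -2.6. The design holds 1 comparison, KO against WT, which asks what the loss of OTUD3, a deubiquitinase of the OTU family, does to transcript levels in white fat in a series on energy metabolism.

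Otud3 (ENSMUSG00000041161, chromosome 4, 138895379 to 138913945, mm10) was lower in each KO library than in both WT libraries. Its normalised read count was 14.96 ± 1.92 CPM in WT (SD, n = 2) and 6.77 ± 1.22 CPM in KO (SD, n = 3), so that KO held 45.3% of the WT level, a log2 fold change of -1.14 (SE 0.21). The counts were 298 and 331 in WT and 142, 109 and 151 in KO. Adjusted over the list alone, among 21 tested OTU deubiquitinases and genes linked to OTUD3, Otud3 was the single member that passed (adjusted p 0.0427 in edgeR). Otulin, which removes linear ubiquitin chains, had a log2 fold change of -0.38 and did not pass. Among 3 further genes of this list, Crebbp, a histone acetyltransferase, had 0.15, Sirt1, a deacetylase, -0.07, and Ppard, a nuclear receptor of fatty acid use, -0.01 (0.01 with upper-quartile scaling), and none of these 3 passed. The list as a set did not pass (camera adjusted p 0.799), with 13 members above 0 and 8 below, a median of 0.02, a mean of -0.05 and an upward test direction. Over all genes, Otud3 missed the threshold in the edgeR quasi-likelihood test (adjusted p 0.181) and passed it in the edgeR exact test (0.0148) and in DESeq2 (0.00262). In the authors' deposited table it stood at a mean FPKM of 4.00 in KO and 9.11 in WT, with a log2 fold change of -1.19 and q 0.222. Counts per gene do not show which exons gave the remaining reads.

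Among single genes, Eda, the ligand ectodysplasin of skin appendage development, was higher in each KO library, at 14.4 ± 0.18 CPM against 2.45 ± 0.54 CPM in WT (SD, n = 3 and n = 2), which is 5.84-fold. Oxtr, the oxytocin receptor, was at 92.7 ± 9.91 CPM in KO and 45.6 ± 0.82 CPM in WT, and Nedd4, a HECT-type ubiquitin ligase, at 1581 ± 107 CPM in KO and 842 ± 70.1 CPM in WT. The other 3 genes of smallest p among those higher in KO were Tmem252 at a log2 fold change of 1.14, Ablim1, an actin-binding LIM protein, at 0.98, and Mapk1ip1 at 0.94. On the lower side C1s1, a protease of the complement system, was at 213 ± 0.52 CPM in KO and 433 ± 21.2 CPM in WT, a log2 fold change of -1.03 (SE 0.07). The other 5 lower genes named by the rule were far lower: Rnase9 at -9.06, Npy, which encodes neuropeptide Y, at -9.06, the ABC transporter Abcb5 at -8.33, Pate2 at -7.82 and Wfdc16 at -7.69. None of these 12 genes passed the edgeR quasi-likelihood test, with adjusted p of 0.0649 or 0.0795, while each of them passed the edgeR exact test, DESeq2 and q 0.05 in the authors' deposited table.

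Over all 17301 genes tested, the edgeR quasi-likelihood test called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 it found 1519 genes, 546 higher and 973 lower in KO, where 865 would be expected by chance. The edgeR exact test called 361 genes (45 higher, 316 lower), DESeq2 456 (123 higher, 333 lower) and limma-voom 0, and the exact test and DESeq2 shared 323. The authors' deposited table has 328 genes at q under 0.05, 28 higher and 300 lower, of which 280 are also among the calls of the exact test. With robust empirical Bayes off, the edgeR quasi-likelihood test called 8 genes, all lower: Abcb5, C1s1, Npy, Pate2, Rnase9, Wfdc16 and, chosen after their values were seen, BC048679 and Gm17252. All KO libraries lay above both WT libraries for 2098 genes and below both for 2432, together 26.2% of genes where chance gives 20%. Without WT 1 the quasi-likelihood count was 391 (25 higher, 366 lower), without WT 2 it was 18 (5 higher, 13 lower), and without any 1 of the KO libraries it was 0.

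**Figure D1:**
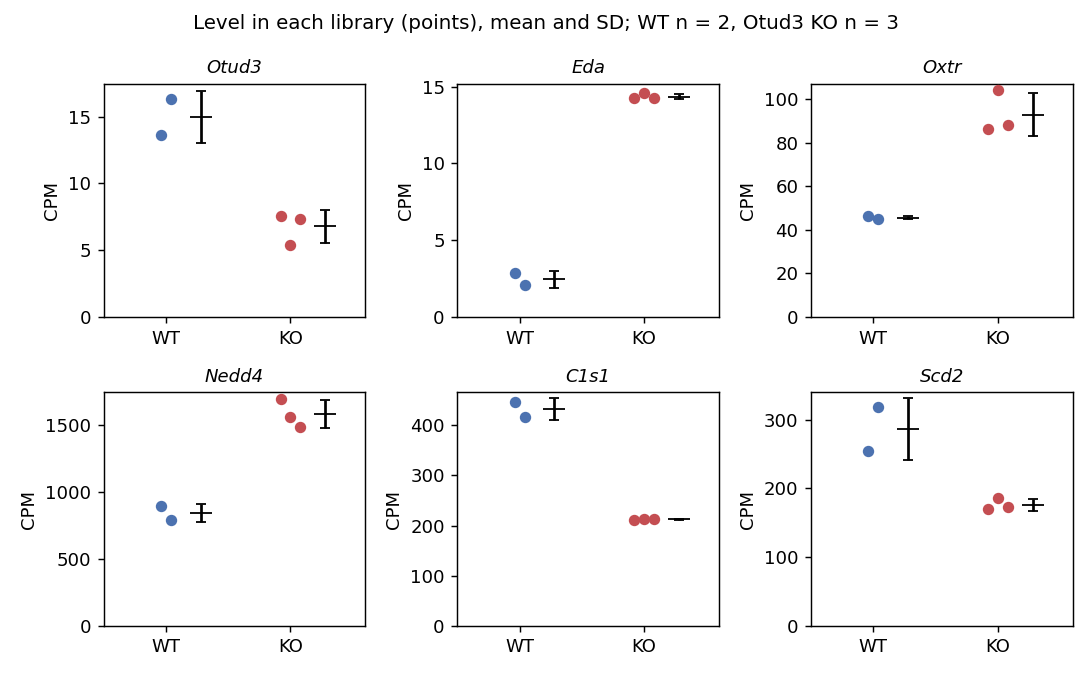
TMM-scaled CPM of Otud3, Eda, Oxtr, Nedd4, C1s1 and Scd2 in each library, with the mean and the SD of the WT (n = 2) and KO (n = 3) groups and each axis starting at 0. The KO libraries lie apart from the WT libraries for each of the 6 genes, as for C1s1 with a mean of 213 CPM in KO and 433 CPM in WT.

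Many transcripts of the male reproductive tract were abundant in both WT libraries and lower in KO, to an extent that differed between KO mice, and some were higher in KO. Rnase9, a ribonuclease-like protein of the epididymis, had 1200 and 2307 counts in WT 1 and WT 2 and 3 counts in each KO library, and Npy, which is outside the list, had 2009 and 4080 counts in WT and 4, 3 and 9 in KO 1, KO 2 and KO 3. Crisp1, an epididymal protein that binds sperm, had 35990 and 82549 counts in WT, 22 in KO 1 and 393 in KO 2, but 26030 in KO 3. Adam7, another epididymal sperm protein, had 5044 and 11351 counts in WT, 85 in KO 1, 2248 in KO 2 and 411 in KO 3. KO 2 alone held many reads of the epididymal lipocalins Lcn8 (982 counts) and Lcn9 (1134 counts) and of Rnase10 (1484 counts), each with at most 12 counts in any other library. The cystatin Cst11 had 737 counts in KO 2, 28 in KO 3 and 0 in the other 3 libraries, at least 181-fold higher in KO against 3 counts over the WT group. It had q 0.00882 in the authors' deposited table, but was not called by the quasi-likelihood test (adjusted p 0.617), the exact test (0.472) or DESeq2 (0.312). Gpx5, an epididymal glutathione peroxidase, had 0 and 2 counts in WT, 1 in KO 1, 3447 in KO 2 and 1008 in KO 3. It was called higher by DESeq2 (adjusted p 0.0158) and in the authors' deposited table (q 0.00034), and not by the exact test (0.153) or the quasi-likelihood test (0.498). Crisp1, Adam7, Lcn8, Lcn9, Rnase10, Cst11 and Gpx5 were chosen after their values were seen.

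As a set, the epididymis and testis list fell, with 11 of its 14 tested members below 0, 3 above and a median log2 fold change of -1.82 (camera adjusted p 1e-07). The list has 18 genes, and Lcn5, Lcn8, Lcn9 and Lcn10 fell under the low-count filter. These went the other way, with 8, 982, 1134 and 181 counts in KO 2 and at most 1 in a WT library. The set test and the list means of each library leave them out. The median with Cst11 at its bound was also -1.82. The call was lost with an estimated correlation (adjusted p = 0.778) and without WT 2 (adjusted p 0.0944), and the adjusted p ranged from 3.01e-23 to 0.778 over all alternatives. Adjusted over the list alone, 4 members were lower, Rnase9, Defb2 at -5.70, Lcn12 at -3.67 and Spag11a at -2.04, the last 2 of them chosen after their values were seen. The mean log2 CPM of the list was 3.22 in WT 1, 4.73 in WT 2, 0.89 in KO 1, 2.91 in KO 2 and 2.17 in KO 3. Families with known roles in the epididymis, taken up after the values were seen, went the same way: 14 of 20 beta-defensins and 11 of 14 WFDC proteins were below 0. The protamine Prm2 of late sperm cells, chosen likewise, had 402 and 2276 counts in WT and 667, 1086 and 217 in KO. The median ratio of WT 2 to WT 1 was 2.04 for the 282 tested genes that are lower in the authors' deposited table, 1.00 for its 27 higher genes and 1.02 for all genes tested. With genes that differed at least 1.5-fold between WT 1 and WT 2 left out, an alternative chosen after seeing the data, the exact test called 90 genes (21 higher, 69 lower) and the quasi-likelihood test 0.

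**Figure D2:**
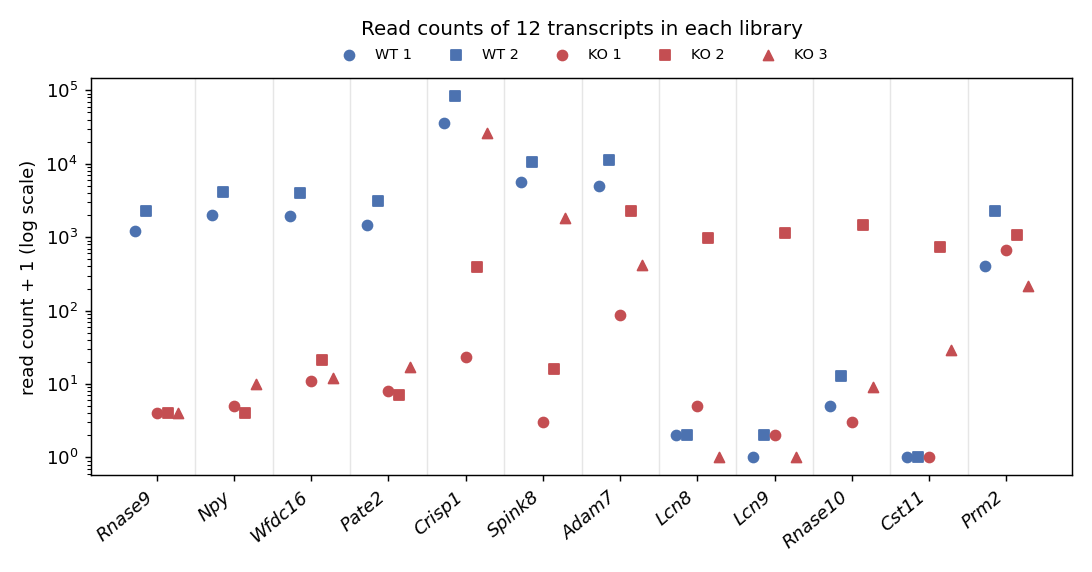
Read counts plus 1 on a log axis for 12 genes described with the epididymis and testis list, in blue for WT and red for KO, with a circle for replicate 1, a square for replicate 2 and a triangle for replicate 3. Rnase9 lies at 3 counts in each KO library, while Crisp1 ranges from 22 counts in KO 1 to 26030 in KO 3 and Lcn9 has 1134 counts in KO 2 alone.

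Epithelial genes fell as well, with 11 of 12 tested members of the mammary and other epithelium list below 0, 1 above and a median of -0.91 (camera adjusted p 1.37e-09). With an estimated correlation the list did not pass (adjusted p = 0.778). Adjusted over the list alone, 6 members were lower. They included Krt18, a keratin of simple epithelium, at 54.8 ± 4.50 CPM in KO (SD, n = 3) and 91.8 ± 9.31 CPM in WT (SD, n = 2), and the adhesion protein gene Cdh1 at 35.1 ± 3.85 and 65.1 ± 13.7 CPM. The other 4 were Epcam at a log2 fold change of -0.39, Krt7 at -0.93, Esrp1 at -1.09 and Cldn3 at -1.75, of which Epcam, Esrp1 and Cldn3 were chosen after their values were seen. DESeq2 called 5 of the list's genes lower and the exact test 4. The list kept its side of the threshold with each library left out.

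The erythrocyte list rose, with 6 of 7 tested members above 0, 1 below and a median of 1.30 (camera adjusted p 3.66e-06), and was past the threshold with each library left out. It did not pass with an estimated correlation (adjusted p = 0.778). Adjusted over the list alone, 3 members passed: the alpha-globin gene Hba-a1 at 17.0 ± 3.05 CPM in KO and 6.92 ± 0.68 CPM in WT, and the beta-globin genes Hbb-bt at a log2 fold change of 1.46 and Hbb-bs, chosen after its values were seen, at 1.39. In the B cell and lymph node list, 3 of 16 members were higher adjusted over the list alone. These were Ighm, the heavy chain of IgM, at 204 ± 35.0 CPM in KO (SD, n = 3) and 113 ± 8.49 CPM in WT (SD, n = 2), the joining chain gene Jchain at a log2 fold change of 1.15, and the kappa chain gene Igkc, chosen after its values were seen, at 1.08. The exact test and DESeq2 called these 3 genes too. The other members did not follow them: 6 members lay above 0 and 10 below, the median was -0.32, the mean -0.09 and the test direction upward, and the list did not pass (adjusted p 0.355). It passed as higher without WT 1 (adjusted p 0.0308) and turned downward without WT 2 (0.191). Of 9 immunoglobulin constant genes, a family taken up after the values were seen, 5 were above 0 and 4 below.

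Insulin signalling rose, with 19 of 24 members above 0, 5 below and a median of 0.11 (camera adjusted p 0.0136). Its members included Pik3ca, the catalytic subunit of PI3-kinase, at 0.41 (SE 0.14). PPAR delta target genes rose with 18 of 25 above 0, 7 below and a median of 0.12 (adjusted p 0.0348), among them the lipoprotein receptor gene Vldlr at 0.58 (SE 0.12). Mitochondrial fatty acid oxidation rose with 15 of 20 above 0, 5 below and a median of 0.13 (adjusted p 0.0491), with Cpt1a, which brings fatty acids into mitochondria, at 0.25 and Acadm, a dehydrogenase of medium chains, at 0.28. Triglyceride storage and lipolysis rose with 16 of 22 above 0, 6 below and a median of 0.20 (adjusted p 0.0493), with Dgat2, which makes triglyceride, at 0.59 (0.39 to 0.85 with a library left out) and Lipe, hormone-sensitive lipase, at 0.27. With an estimated correlation none of the 4 lists passed (adjusted p = 0.778, and 0.785 for fatty acid oxidation). No member of the 4 passed over all genes or adjusted over the list alone in edgeR, although the exact test and DESeq2 called Vldlr. The lists overlap: 13 of the 25 PPAR delta targets and 10 of the 20 oxidation genes stand in other lists too. None of the 4 passed without KO 1, where the medians were 0.07 for insulin signalling, 0.05 for PPAR delta targets, 0.01 for fatty acid oxidation and 0.08 for triglyceride storage. None passed without WT 2 either, where PPAR delta targets had 0.06 and triglyceride storage 0.11. With the mean of the epididymis and testis list as a covariate, an alternative chosen after seeing the data, none passed and 3 turned downward: PPAR delta targets (adjusted p 0.819), fatty acid oxidation (0.441) and triglyceride storage (0.58), with insulin signalling at 0.866. Without WT 1 insulin signalling alone of the 4 passed, and PPAR delta targets had a median of 0.20. A replicate block ended all 4 calls, the filter at 1 CPM those of fatty acid oxidation (0.0588) and triglyceride storage (0.0607), and the size factors of DESeq2 that of triglyceride storage (0.0506). Over all alternatives and the 4 lists the adjusted p ranged from 0.00159 to 0.866.

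The stearoyl-CoA desaturases, which make monounsaturated fatty acids, went opposite ways. Scd2 was at 176 ± 8.63 CPM in KO (SD, n = 3) and 286 ± 45.4 CPM in WT (SD, n = 2), a log2 fold change of -0.70 (SE 0.12). It passed adjusted over the list alone (0.0294), in the exact test (0.0044) and in DESeq2 (2.57e-05). Scd1, more than 100 times as abundant, had a log2 fold change of 0.51 (SE 0.12) and passed in DESeq2 (0.00175) alone. De novo lipogenesis as a list did not pass, with 15 of 21 members above 0, 6 below and a median of 0.11 (camera adjusted p 0.32). The tricarboxylic acid cycle had 22 of 24 members above 0, 2 below and a median of 0.08, and did not pass (adjusted p 0.0574), with Mdh1 at 0.21 and Idh2 at 0.18. Glucose uptake and glycolysis had 15 of 19 above 0, 4 below and a median of 0.13 (adjusted p 0.0807), with Eno1 at 0.32, which DESeq2 called, and Aldoa at 0.23. Nuclear-encoded oxidative phosphorylation did not pass, with 44 of its 76 members above 0, 32 below, a median of 0.018, a mean of -0.004 and an upward test direction (adjusted p 0.548), and its subunit genes Ndufa6 and Ndufb11 were at -0.20 and -0.19 (-0.23 to -0.13 and -0.26 to -0.10 with a library left out). Its direction depended on the libraries and the model: it passed as higher without KO 2 (adjusted p 0.0129), passed as lower with the epididymis and testis covariate (0.00172), and was downward without WT 2 (0.57) and without KO 1 (0.45). Without KO 2 the tricarboxylic acid cycle (0.00159), glucose uptake and glycolysis (0.0129) and de novo lipogenesis (0.032) passed as higher too. The 13 mitochondrially encoded protein genes had 3 members above 0, 10 below and a median of -0.03 (adjusted p 0.783), with mt-Nd6 at -0.33 and mt-Nd2 at -0.17 (-0.41 to -0.21 and -0.295 to 0.003 with a library left out). Cholesterol synthesis had 8 of 22 above 0, 14 below and a median of -0.17 (adjusted p 0.355), with Fdps at -0.90.

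**Figure D3:**
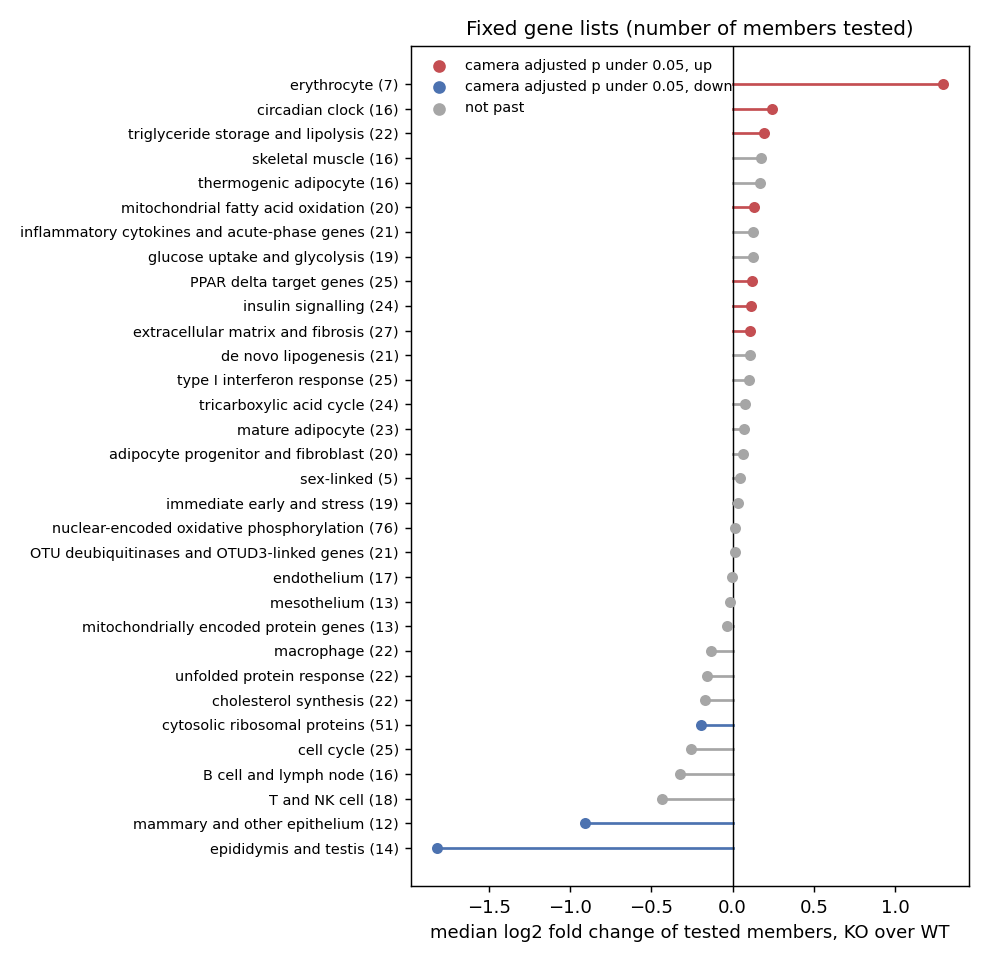
Median log2 fold change, KO over WT, of the 32 gene lists with the number of tested members in brackets, in red for lists higher and in blue for lists lower in KO past the camera threshold and in grey for the rest. The epididymis and testis list has the lowest median at -1.82 and the erythrocyte list the highest at 1.30.

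The clock list rose, with 11 of 16 members above 0, 5 below and a median of 0.24 (camera adjusted p 0.00506), but not with an estimated correlation (adjusted p = 0.778) or without WT 2 (adjusted p 0.207; 0.00186 to 0.778 over all alternatives). The call was also lost with the epididymis and testis covariate (0.645) and a replicate block (0.104). Adjusted over the list alone, 3 members passed: the transcription factor genes Tef at 0.51 (SE 0.09) and Nr1d2 at 0.54 (SE 0.11), and Nr1d1, chosen after its values were seen, at 0.56 (SE 0.12). Nr1d1 and Nr1d2 encode the REV-ERB receptors, which repress transcription within the clock. DESeq2 called these 3 genes, the exact test called Nr1d2. Extracellular matrix and fibrosis genes rose with 21 of 27 above 0, 6 below and a median of 0.11 (adjusted p 0.0348), with the collagen gene Col5a1 at 0.30 and the elastin gene Eln, against the direction of the list, at -0.32 (-0.43 to -0.17 with a library left out). That list did not pass with an estimated correlation (adjusted p = 0.778), without WT 2 (adjusted p 0.57) or without KO 1 (0.0723), nor with the epididymis and testis covariate (0.843) or a replicate block (0.0522), with 0.00326 to 0.843 over all alternatives. 

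The cytosolic ribosomal protein list fell as a set, with 49 of 51 members below 0, 2 above and a median of -0.19 (camera adjusted p 8.33e-06). No member passed over all genes or adjusted over the list alone, the exact test called 0, and all KO libraries lay below both WT libraries for 28 members. Rps3 was at 188 ± 5.81 CPM in KO (SD, n = 3) and 240 ± 13.2 CPM in WT (SD, n = 2). The list did not pass with an estimated correlation (adjusted p = 0.778), nor without WT 1 (adjusted p 0.636; 6.66e-09 to 0.778 over all alternatives), where its median was -0.07. The members that DESeq2 called lower included Rps3 and Rplp0, the latter chosen after its values were seen. The unfolded protein response list had 8 of 22 members above 0, 14 below and a median of -0.16, and did not pass (adjusted p 0.0694). Its member Manf, a factor secreted under stress of the endoplasmic reticulum, was at 29.2 ± 2.28 CPM in KO and 47.5 ± 7.19 CPM in WT and passed adjusted over the list alone (0.0457), in the exact test and in DESeq2. The chaperone gene Canx had -0.35 and passed in DESeq2 alone.

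Markers of fat cells as a whole did not pass. The mature adipocyte list had 13 of 23 members above 0, 10 below and a median of 0.07 (camera adjusted p 0.32), with Nnat at 0.48 and Lipe at 0.27, and the thermogenic adipocyte list 10 of 16 above 0, 6 below and a median of 0.17 (adjusted p 0.297), with Ppara at 0.62 and Gk at -0.62. Progenitors and fibroblasts had a median of 0.06 (11 above 0, 9 below; adjusted p 0.689), with Ly6a at -0.44 and Sema3c at 0.30. The endothelium list had a median of -0.001, a mean of 0.002 and an upward test direction (8 above 0, 9 below; adjusted p 0.639), with Eng at -0.41 and Erg at 0.30. Mesothelium had a median of -0.02 (5 above 0, 8 below; adjusted p 0.975; lower at 0.000214 with the epididymis and testis covariate), with Krt7 at -0.93 and Krt19 at 0.81, both of which stand in the epithelium list too. Skeletal muscle had a median of 0.18 (9 above 0, 7 below; adjusted p 0.548), with Ttn at -1.89 and Casq1 at 1.19. Several of these values moved by over 1.5 times with a library left out: Ppara ranged from 0.33 to 1.04, Nnat from 0.22 to 0.84, Ly6a from -0.57 to -0.26, Eng from -0.62 to -0.14, Krt19 from 0.360 to 1.113, Ttn from -2.37 to -1.07 and Casq1 from 0.63 to 1.48.

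Immune and stress lists did not pass with all 5 libraries, and several passed with 1 left out. Macrophage genes had 5 of 22 members above 0, 17 below and a median of -0.13 (camera adjusted p 0.084), with Atp6v0d2, a subunit of the proton pump of lysosomes, at -0.97 and the complement gene C1qb at -0.26. This list passed as lower without WT 2 (adjusted p 0.00447) and without KO 2 (0.0138), and turned upward without WT 1 (0.746). The type I interferon response had 19 of 25 above 0, 6 below and a median of 0.10 (adjusted p 0.0765), with Rsad2 at 0.44 and Ifit3 at 0.40. T and NK cell genes had a median of -0.44 (6 above 0, 12 below; adjusted p 0.297), with Klrb1c at 2.43, owing to 206 counts in KO 2 against 14 to 19 in the other libraries, and Ncr1 at -0.71. With a library left out Klrb1c ranged from 0.31 to 2.91 and Ncr1 from -0.94 to -0.40. Inflammatory cytokines and acute-phase genes had a median of 0.13 (11 above 0, 10 below; adjusted p 0.348), with Cxcl1 at 1.33 and Serpina3n at 0.41 (0.27 to 0.62 with a library left out). Immediate early and stress genes had a median of 0.04 (11 above 0, 8 below; adjusted p 0.129), with Jun at 0.34, which DESeq2 called, and Zfp36 at 0.43. Cell cycle genes had 5 of 25 above 0, 20 below and a median of -0.25 (adjusted p 0.355), with Mcm2 at -0.56 and Pcna at -0.27. Without KO 1 the cell cycle list passed as lower (adjusted p 0.0319), while it turned upward without WT 2 (0.207), without KO 3 (0.919) and with a replicate block (0.792). The unfolded protein response passed as lower without KO 1 (0.0351). Without KO 2, the unfolded protein response passed as lower (0.0476), and the type I interferon response (0.00795) and the immediate early and stress list (0.0476) as higher.

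Each library held reads of the Y-linked genes: Ddx3y had 1667 to 2267 counts, Eif2s3y 896 to 1304, Kdm5d 754 to 953 and Uty 456 to 549, while Xist, which is expressed from an inactive X chromosome, had 8 to 20. Their log2 fold changes were 0.14 for Ddx3y, 0.17 for Kdm5d, 0.05 for Uty, -0.08 for Eif2s3y and -0.09 for Xist. With a library left out Ddx3y ranged from 0.05 to 0.21 and Kdm5d from 0.06 to 0.31, and Uty, Eif2s3y and Xist took both signs. None of the 5 passed, nor did the sex-linked list (median 0.05, 3 above 0, 2 below; camera adjusted p 0.515).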

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

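The covariate fit and the fits without genes that differ between WT 1 and WT 2 were chosen after the results were seen, the other alternatives before. The count of 0 genes in the edgeR quasi-likelihood test was the same with both other scalings, limma-voom, both other filters, the added fold threshold, the covariate and the gene exclusion. It was 456 with DESeq2, 361 with the edgeR exact test, 8 with robust empirical Bayes off, 26 with a replicate block and 90 with the exact test after the gene exclusion, and 0 to 391 with each library left out. DESeq2 changed the size factors and the gene filter (19339 genes) along with the test. The cause of these differences was not tested. A block has no ground in the labels, and across genes the residuals of equal replicate numbers correlated by 0.125 and 0.316 in the 2 pairs that can be formed, too few to tell.

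Otud3 was lower under every alternative run, from -1.001 to -1.299 in log2 fold change, and passed the threshold in DESeq2 (-1.14) and the exact test (-1.14). Of the 32 lists, 10 passed in camera. The count was 9 with the size factors of DESeq2, 8 of 31 with the 1 CPM filter and 10 with cell type genes removed, but 0 with an estimated correlation, 0 with fry by direction, 0 with fry mixed, 4 with the replicate block, 5 with the covariate and 4 to 18 with each library left out. The covariate was lower in each KO library (0.89 to 2.91) than in both WT libraries (3.22 and 4.73). Lost, reversed or new calls in that fit therefore cannot be laid to tract content. The covariate is also a mean of 1 of the lists, so that its own fit for that list says little, and 3 of the 10 lists were still past in it. The other 2 of the 5 were new: nuclear-encoded oxidative phosphorylation (0.00172) and mesothelium (0.000214), both lower. The cause of these changes was not tested.

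For named genes, 1002 of the values under alternatives had the direction and the side of the threshold of the main value, 85 moved past the threshold in the same direction and 15 reversed. All reversals were in genes near 0 that passed nowhere. The log2 fold change of 24 of the 79 named genes moved by over 1.5 times with a library left out, and of these 24 the exact test and DESeq2 called 0. Crebbp was among them, with a range of 0.099 to 0.235. Ppard had 0.012 with upper-quartile scaling, 0.001 with DESeq2 and 0.015 without a filter, and Eif2s3y 0.079 with the block. With each library left out, Ppard ranged from -0.096 to 0.103, Eif2s3y from -0.181 to 0.089, Xist from -0.576 to 0.357, Sirt1 from -0.154 to 0.017, mt-Nd2 from -0.295 to 0.003 and Uty from -0.012 to 0.147. The cause was not tested. Lcn8 and Lcn9 lie under the low-count filter, since a single library holds nearly all of their reads. At these group sizes 26% of simulated 2-fold changes were recovered, 76% of 4-fold and 90% of 8-fold and of 16-fold ones. In the data, 182 genes were at least 8-fold lower at an unadjusted p under 0.05 in the quasi-likelihood test, and 5 were higher. The count past the threshold was still 0, so that the simulated shares do not describe these genes. Whether group size accounts for the count of 0 thus stays open.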

Other observations

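All tests of the hypotheses below were chosen after the results were seen, except the count of other splits of the libraries; the KEGG terms, the chromosome counts and the testis lists were also chosen then.

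Of the genes that both the edgeR exact test and DESeq2 called and that lay within 1.5-fold between WT 1 and WT 2, 112 remained, 40 higher and 72 lower. The lower ones still hold genes of the tract and epithelium lists, Defb2 at -5.70, Krt18 at -0.75 and Cdh1 at -0.89, and the beta-defensin Defb9 at -7.24, so that this choice of genes did not remove tract content. Cbs, which makes cystathionine from homocysteine, had a log2 fold change of -1.90, Cth, which makes cysteine from it, -1.61, and Suox, which oxidises sulfite, -0.96. The transcription factor gene Arnt2 had -1.89, Syn2, a synaptic vesicle protein gene, -1.42 and the exonuclease gene Isg20 -1.40. On the higher side, Slc8a1, a sodium and calcium exchanger, had 1.23, and Mest, an imprinted gene linked to fat cell size, had 1.23 with 7165 and 8817 counts in WT and 23343, 16753 and 12498 in KO. These genes were chosen after their values were seen and did not pass the quasi-likelihood test. The 1.5-fold limit used the same WT libraries as the tests, so that it favours genes whose WT values lie close by chance. The KEGG terms closest to Cbs, Cth and Suox did not pass: Cysteine and methionine metabolism had 20 genes above 0 and 21 below (camera adjusted p 0.57), and Sulfur metabolism had 4 above and 6 below (0.61).

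Of 278 KEGG terms with 10 to 300 tested members, 7 passed camera with the preset correlation and 0 with an estimated one (smallest adjusted p 0.801). The Ribosome term was lower (127 genes, 23 above 0 and 104 below, adjusted p 0.00151). Collecting duct acid secretion was lower too (adjusted p 0.0118), with 9 of 23 genes above 0, 14 below and a median of -0.10. Higher were Oxytocin signaling pathway (136 genes, 0.0118), Hypertrophic cardiomyopathy (65 genes, 0.0309), Olfactory transduction (41 genes, 0.0327), Endocrine and other factor-regulated calcium reabsorption (39 genes, 0.041) and Insulin signaling pathway (129 genes, 87 above 0 and 42 below, 0.041). On the X chromosome, 36 of 582 genes had an unadjusted p under 0.01, 6.19% against 2.89% of all genes (odds ratio 2.31, 1.58 to 3.29, Fisher's exact p 2.1e-05). Among genes within 1.5-fold between WT libraries it was 16 of 445 (odds ratio 1.93, 1.08 to 3.24, Fisher's exact p 0.0209). With a Benjamini-Hochberg adjustment over 20 chromosomes, the latter Fisher's exact p was 0.303. Both tests treat genes as independent. Within 10 Mb of Otud3, 3 of 279 genes had an unadjusted p under 0.01, against 2.8% of other autosomal genes (odds ratio 0.377, 0.077 to 1.12). KO 3 alone had reads of the muscle gene Ckm (409 counts, at most 4 elsewhere) and of Elf5 (86 counts, at most 3 elsewhere). Testis germ cell genes summed to 1331 and 13282 counts in WT 1 and WT 2 and to 2038, 3461 and 1077 in the KO libraries, and Leydig cell genes to 426 and 1446 in WT and 129, 502 and 287 in KO.

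The first pattern weighed is the lower level of reproductive tract transcripts in KO. The counts go against a knockout that lowers all list members alike in each mouse. Of the 14 members, 6 lay more than 10-fold apart between KO libraries, and no random list of like level had more than 3. The 6 include Rnase10 and Cst11, which were higher in KO, while Rnase9 had 3 counts in each KO library. This comparison was prompted by the uneven KO counts too, so that it describes them and is no independent test. Ratios to WT 1 among 5 abundant members spanned 172-fold even in KO 3, where the range was smallest. That argues against 1 kind of tract tissue in different amounts. A candidate explanation is that different parts of epididymis and testis were taken with the fat; it was prompted by the uneven KO counts, so that the median range of 2.08 log2 units between KO libraries, against 1.37 at most in 10000 random lists of like level, restates them and is no independent support. Still open is whether the knockout acts on the 68 genes of at least 1 CPM in both WT libraries that were more than 10-fold below both in each KO library (1 gene of at least 1 CPM in every KO library went the opposite way), since a tract region missing from the KO fat cannot be told apart from it without tract samples. The median ratio of WT 2 to WT 1 was 2.21 for these 68 genes and 1.02 for all genes tested. That ratio compares WT mice only and so cannot decide the question. The labels name no tract tissue.

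The second pattern is the upward shift of the insulin, PPAR delta, fatty acid oxidation and triglyceride lists. It may rest on KO 1: 0 of the 4 lists passed without KO 1, with a median of medians of 0.06 in place of 0.13 (0.01 in place of 0.13 for fatty acid oxidation), while all 4 passed without KO 2 and without KO 3. The median of medians was 0.10 without WT 2 and 0.184 without WT 1. With the epididymis and testis score as a covariate none of the 4 lists passed and 3 turned downward (camera adjusted p 0.441 to 0.866 for the 4). That score was lower in each KO library than in both WT libraries, so that lost calls in this fit cannot be laid to tract content. KO 1 has the lowest score, so that KO 1 and tract content were not separated. Whether a higher share of fat cell RNA lies behind it stays open, since the 12 fat cell markers outside these lists went both ways, with a median of 0.025, a range of -0.23 to 0.48 and 5 of them above the median list member at 0.13. An effect of the knockout was not excluded by any of these values.

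The third pattern is the lower level of cytosolic ribosomal protein genes. Transcript length is argued against, since random lists matched on length and level had a median of -0.013, against -0.191 for the ribosomal list. That value also lay below each of the 10000 matched lists, the lowest of which reached -0.14. Whether more tract epithelium in the WT fat plays a part stays open. These genes were lower in WT 2, the library with more tract transcripts, than in WT 1 (median log2 ratio -0.155, 7 of 51 higher). That sets 1 library against 1 and cannot decide, since a high level in WT 1 for any other reason would give the same ratio. Much of the shift may rest on WT 1, since without it the median was -0.072 and the list no longer passed (adjusted p 0.636; 6.66e-09 to 0.778 over all alternatives), although 37 of 51 members stayed below 0 and 0.01% of the matched lists were as low in that fit. The matched lists drew genes independently in both fits, while the correlation estimated for the ribosomal list was 0.292. How unusual the shift is thus cannot be read from the matched lists. An effect of the knockout stays open.

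For the genes at an unadjusted p under 0.05, the 10 splits of the 5 libraries into 2 and 3 are too few for a share under 0.05. The real split gave 1519 genes, the highest of the others, WT 2 and KO 3 against the rest, 1041, and 1 split gave as many as the real one, the real one itself. At an adjusted p under 0.05 the real split gave 0 genes, and KO 2 and KO 3 against the rest gave 2.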
